A study of Mus musculus with 2 samples.

How the data were processed

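Per the labels' protocols, total RNA was extracted with Trizol from mouse primary hepatocytes and made into libraries with an Illumina TruSeq RNA kit. Per the submitters' processing notes, Bowtie 0.12.2 and the mm8 build of the mouse genome were used. The series' design text also names BWA followed by ANOVA, and TopHat followed by Cufflinks, but the same text speaks of retinal profiles in triplicate, so it may describe another study in part. The files hold 1 table per condition, treated as 1 library, and no label says whether reads of several cultures were pooled in it. The gene models, the counting rule and the treatment of reads with several matches are not stated in any label.

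The authors deposited 1 table per library with FPKM values, that is reads per kilobase of gene model and 1000000 reads, for 35129 gene symbols with 1 value each. The reads behind the values can be recovered. Within a gene the ratio of both libraries is a ratio of whole numbers times 1 constant for 19640 of the 19667 genes above 0 in either library (99.9%, relative tolerance 1e-11). Matching the steps gave totals of 11151711 reads for Ad-KLF14 and 11311344 for Ad-GFP. Candidate totals differed by whole factors, and the choice used the gene lengths implied by 679 low genes with equal reads in both libraries. Of those with a reference, only 19.8% lay within 1% of a transcript length, so the totals may be off by such a factor. The number of reads per gene was taken as the smallest pair of whole numbers that fits, and in 969 of the kept genes it was divided by up to 6 where the implied gene length exceeded every reference transcript, as reads split between places would give. These numbers are therefore lower limits where reads were not split. They served for the counting intervals, the share of reads from Klf14, the alternative without Klf14 reads, redraws of the libraries and the floor for genes without reads, and all ratios of named genes come from the FPKM values. In a simulation of 25678 genes with whole reads and reference gene lengths, both totals were recovered. Of the read numbers 83.6% were exact and 0% were too high. No reads were split between places in it, so it does not show how often split reads make the numbers too high. Of the intervals of 10640 genes, computed from the true and not the recovered read numbers, 95.5% held the true ratio. In a gene of 2000 bases, 3 reads are worth 0.135 FPKM in the Ad-KLF14 library and 0.133 FPKM in the Ad-GFP library.

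Log2 ratios are Ad-KLF14 minus Ad-GFP on log2(FPKM + 1), which understates differences of low genes. Folds of named genes are ratios of the FPKM values without the pseudocount. Genes with a mean of at least 1 FPKM over both libraries were kept, 12419 in all. Genes were counted as apart from 2-fold on. The 95% interval of a ratio is the exact Clopper-Pearson interval of the reads of a gene in both libraries, rescaled by the totals. It covers counting error only and says nothing of differences between cultures. Against a library with 0 reads, the ratio was computed from a floor of 3 reads, which leaves out the counting error of the other library.

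Each gene list was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list is called outside the limits below percentile 2.5 or above 97.5. Lists with fewer than 5 measured members got no percentile. The percentile describes these libraries and is no test of the conditions. In simulated libraries, a list of 25 genes shifted by a log2 of 1.5 upward lay at percentile 100 and a list shifted downward at 0. Of 100 unshifted lists 8 lay outside the limits. The simulated shift was larger than any list median below, and unshifted genes differed by counting error only. The simulation therefore does not show how lists with smaller shifts would rank.

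The filter, the pseudocount, the fold, 34 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists, 8 on glucose, lipid, bile acid and insulin genes were primary, since KLF14 has been studied in hepatocytes for metabolism, and the others gave context or marked other cell types. The rule names Klf14, Apoa1, Ppargc1a, Pck1, G6pc and Alb, the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among genes with a mean of at least 5 FPKM, up to 4 measured members of a list with the largest log2 ratios, and the 3 genes with the highest mean. Another 8 lists (V-ATPase, proteasome, lipid droplet, E2F, CDK inhibitor, mitochondrially encoded, SRF target and YAP-TEAD target genes) were chosen after values had been seen and stand in the closing section only.

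Alternatives were pseudocounts of 0.1 and 5 FPKM, scaling to a trimmed mean of log ratios (30% trimmed from each end), to the upper quartile or to a sum of 1000000, removal of a running median along expression over 501 genes, no filter or a mean of at least 5 FPKM, folds of 1.5 and 4, random lists without matching, and the mean in place of the median. Chosen after seeing the data were the removal of Klf14 reads from the library total, a requirement that the counting interval excludes 1, and the removal of running medians along transcript GC content and length. GC content and length came from GENCODE transcripts of build GRCm38, which is not the submitters' build, matched by symbol for 11794 of the kept genes (95.0%), and no coordinates are given. Symbols with near-identical copies are uncertain. Gapdh, checked after its values were seen, stood at only 3.06 and 3.09 FPKM, and the mitochondrial COX2 at 17.6 and 15.4 FPKM beside COX1 at 8734 and 7776, so levels of genes with copies elsewhere in the genome are uncertain. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.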

Results

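Transcript levels were measured by RNA sequencing in primary hepatocytes of C57BL/6 mice infected with an adenovirus that carries the zinc finger transcription factor KLF14 (Ad-KLF14) or with a control adenovirus labelled GFP (Ad-GFP). The comparison asks which transcripts differ when hepatocytes are made to express KLF14. Each group holds 1 table of values, treated here as 1 library, so there are no replicates, no test between the conditions was possible, and every difference below describes these 2 libraries. The series' design text speaks of triplicates, and whether a table pools the reads of several cultures is not stated. The values are FPKM for 35129 gene symbols. Read totals of 11151711 in the Ad-KLF14 library and 11311344 in the Ad-GFP library were recovered from them. The match of these totals to reference gene lengths was weak, so they may be off by a whole factor. In the Ad-KLF14 library 18348 genes had a value above 0, and in the Ad-GFP library 18263 did. A total of 12419 genes, 11258 of them typed as mRNA in the files, had a mean of at least 1 FPKM and entered the comparison.

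Klf14 stood at 13164 FPKM in the Ad-KLF14 library, from at least 217993 reads or 1.95% of its total (95% Clopper-Pearson interval 1.95% to 1.96%), and at 0.298 FPKM from 5 reads in the Ad-GFP library. The ratio was 44223 (95% counting interval 18950 to 136198). Reads of the virus insert and of the endogenous gene were not told apart. Klf14 was among the 3 genes with the highest mean level, with the mitochondrial COX1 (8734 against 7776 FPKM, Ad-KLF14 first here and below) and the haem carrier hemopexin, Hpx (4356 against 5698 FPKM). Albumin, Alb, was at 4172 against 5115 FPKM, a ratio of 0.816 (interval 0.804 to 0.828).

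Most other genes lay close together in both libraries. On log2(FPKM + 1), 791 genes (6.37%) were at least 2-fold higher with Ad-KLF14 and 1117 (8.99%) at least 2-fold lower, while 7742 (62.3%) lay within 1.5-fold. The median log2 ratio was −0.03, and the standard deviation across genes without Klf14 was 0.73. With Klf14 reads left out of the library total, the median was −0.003, and 851 genes were higher and 1061 lower. These counts use the pseudocount, so a low gene can count as under 2-fold although its FPKM ratio, given below as its fold, is larger. Across genes the libraries correlated with Pearson's r of 0.92, where genes are not independent replicates.

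**Figure D1:**
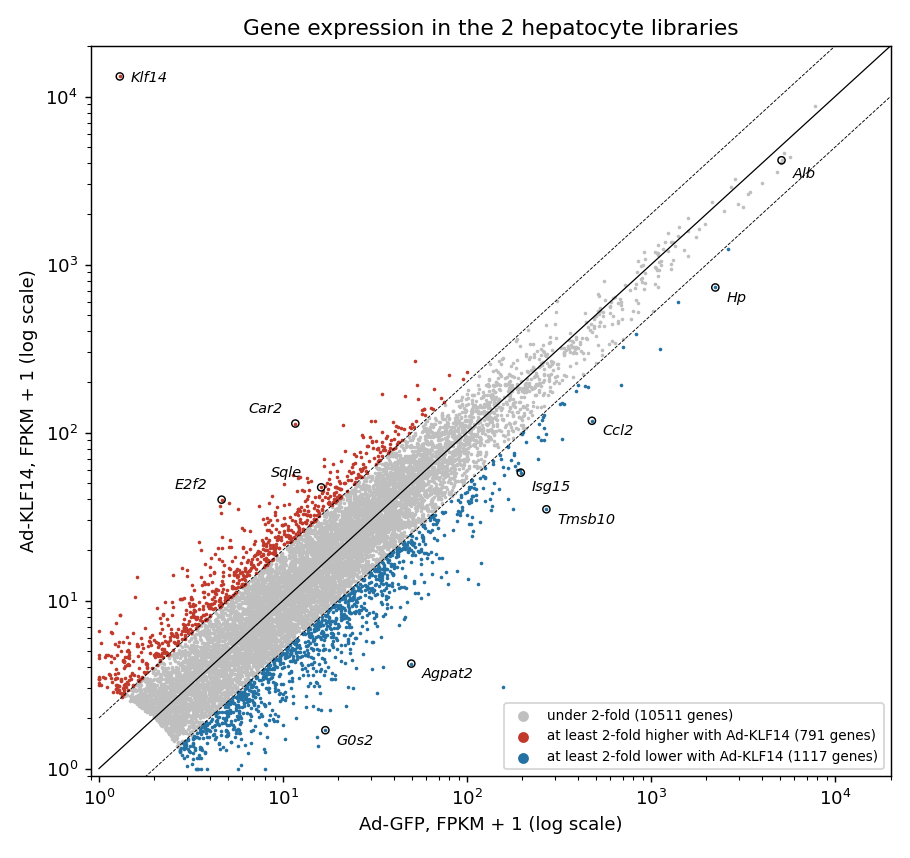
Level of each of the 12419 genes in the Ad-GFP library (horizontal) and the Ad-KLF14 library (vertical), as FPKM + 1 on log axes; the solid line marks equal levels, the dashed lines 2-fold differences, and circles mark genes named in the text. Klf14 lies far above all others, 791 genes are at or above the upper dashed line and 1117 at or below the lower.

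After Klf14, the genes with the largest positive log2 ratios among those with a mean of at least 5 FPKM included carbonic anhydrase 2, Car2, at 112 against 10.7 FPKM (10.5-fold, counting interval 8.62 to 12.9), and the cell cycle transcription factor E2f2 at 38.9 against 3.64 FPKM (10.7-fold, interval 9.22 to 12.4). Fam123a was 20.8-fold higher, the transcriptional coregulator Cited1 10.1-fold, the phosphatase gene Pdxp 8.97-fold, the membrane-bound metalloproteinase gene Mmp17 8.88-fold, Zkscan14 7.27-fold and Abhd15 8.62-fold. Ccno was at 9.56 against 0.566 FPKM, and the interval of the 16.9-fold ratio runs from 5.46 to 84.7. The Ad-GFP value of Ccno rests on at least 3 reads, a lower limit, so its interval may be too wide. A pair of gene models without curated names completed these 12 genes.

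Among the 12 genes with the largest negative log2 ratios, the largest difference was that of LOC100048884, a gene model without a curated name, at 2.08 against 155 FPKM (74.5-fold lower, interval 55.4 to 103). Agpat2, which makes phosphatidic acid on the way to triglyceride, was at 3.21 against 48.8 FPKM (15.2-fold lower, interval 8.04 to 32.3). The Ad-KLF14 value of Agpat2 rests on at least 10 reads, a lower limit, so its interval may be too wide. G0s2, the inhibitor of adipose triglyceride lipase, was at 0.691 against 16 FPKM (23.1-fold lower, interval 10.7 to 61.0), and Isyna1, which makes inositol phosphate from glucose 6-phosphate, was 11.3-fold lower. The chemokine gene Ccl20 was 13.8-fold lower and the transporter gene Slc4a11 26.8-fold lower, while Aig1 was 10.1-fold lower and Defb36 15.6-fold lower. Prelid2 (39.1-fold lower) and tissue factor, F3 (11.5-fold lower, interval 3.63 to 58.5), each rest on at least 3 reads in the Ad-KLF14 library. As this is a lower limit, the interval of F3 may be too wide. Serf1 was 17.2-fold lower, from at least 12 against 209 reads. Mup17 was 9.73-fold lower, but it has near-identical copies in the genome whose reads could have been shared out, so its value is uncertain.

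Among genes of glucose metabolism, the coactivator of gluconeogenesis Ppargc1a was higher with Ad-KLF14, at 2.58 against 0.558 FPKM (4.63-fold, interval 3.28 to 6.66). The gluconeogenic enzyme genes Pck1 and G6pc were close to the floor. Pck1 was at 0.480 against 0.642 FPKM from 14 and 19 reads (ratio 0.747, interval 0.347 to 1.57), and G6pc at 0.479 against 0.158 FPKM from 12 and 4 reads (ratio 3.04, interval 0.922 to 12.9), so a difference was not detectable at this depth in either. Fbp1 was 2.93-fold lower (7.13 against 20.9 FPKM) and the mitochondrial Pck2 was 5.54-fold lower (3.01 against 16.7 FPKM), whereas the transaminase gene Got1 was 1.93-fold higher. Of 13 measured gluconeogenesis genes, 9 were above 0 on the log2 ratio, 1 at least 2-fold higher and 2 at least 2-fold lower. Their median log2 ratio of 0.49 was at percentile 99.1 among random lists of the same size and expression, but the mean of 0.12 was only at percentile 81.8, and with a pseudocount of 5 FPKM the median was 0.32 (percentile 98.6). The 21 glycolysis genes had a median of −0.24 (percentile 10.4), with the liver phosphofructokinase gene Pfkl 2.32-fold lower and Pklr 1.74-fold lower. Insulin signalling genes had a median of −0.44 over 15 members (percentile 3.75), inside the limits but below them under 3 alternatives. Among them the inhibitor of Akt signalling Trib3 was 2.84-fold lower, Igfbp1 1.92-fold lower and Socs3 2.09-fold higher.

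Cholesterol synthesis genes were higher as a group. Of 24 measured members 19 were above 0, 7 at least 2-fold higher and 1 at least 2-fold lower, and the median of 0.65 was at percentile 100. Idi1 was 5.48-fold higher (16.9 against 3.08 FPKM, interval 4.42 to 6.85), Mvd 4.94-fold (9.38 against 1.90 FPKM), squalene epoxidase, Sqle, 3.05-fold (46.2 against 15.1 FPKM) and the sterol carrier gene Stard4 2.90-fold. Apolipoprotein genes lay closer together. Apoa1, the main protein of HDL, was at 185 against 210 FPKM, a ratio of 0.882 (interval 0.831 to 0.936), and of 19 measured genes of the HDL and apolipoprotein list 18 were under 2-fold, with a median of −0.12 (percentile 31.2). Apof was 2.31-fold lower in it and Mttp, which loads lipid onto apolipoprotein B, 1.84-fold higher.

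Fatty acid genes went in both directions. Fatty acid synthase, Fasn, was 2.31-fold higher (35.7 against 15.4 FPKM) while Agpat2 was lower, and the list of 18 synthesis genes had a median of 0.12 (percentile 73.6) and a mean of the opposite sign, −0.09. In fatty acid oxidation, Acads was 3.59-fold lower (10.2 against 36.6 FPKM) and Hadh 2.74-fold lower, and Hadhb, a subunit of the trifunctional protein, was 2.39-fold higher. The 19 oxidation genes had a median of 0.01 (percentile 50.6) and a mean of −0.24. In bile acid synthesis and transport, the canalicular exporter gene Abcc2 was 2.36-fold higher (97.3 against 41.3 FPKM), Cyp27a1 2.08-fold higher and Nr0b2, which encodes the repressor SHP, 2.61-fold lower. The 12 measured members had a median of −0.03 (percentile 46.6) and a mean of 0.02.

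**Figure D2:**
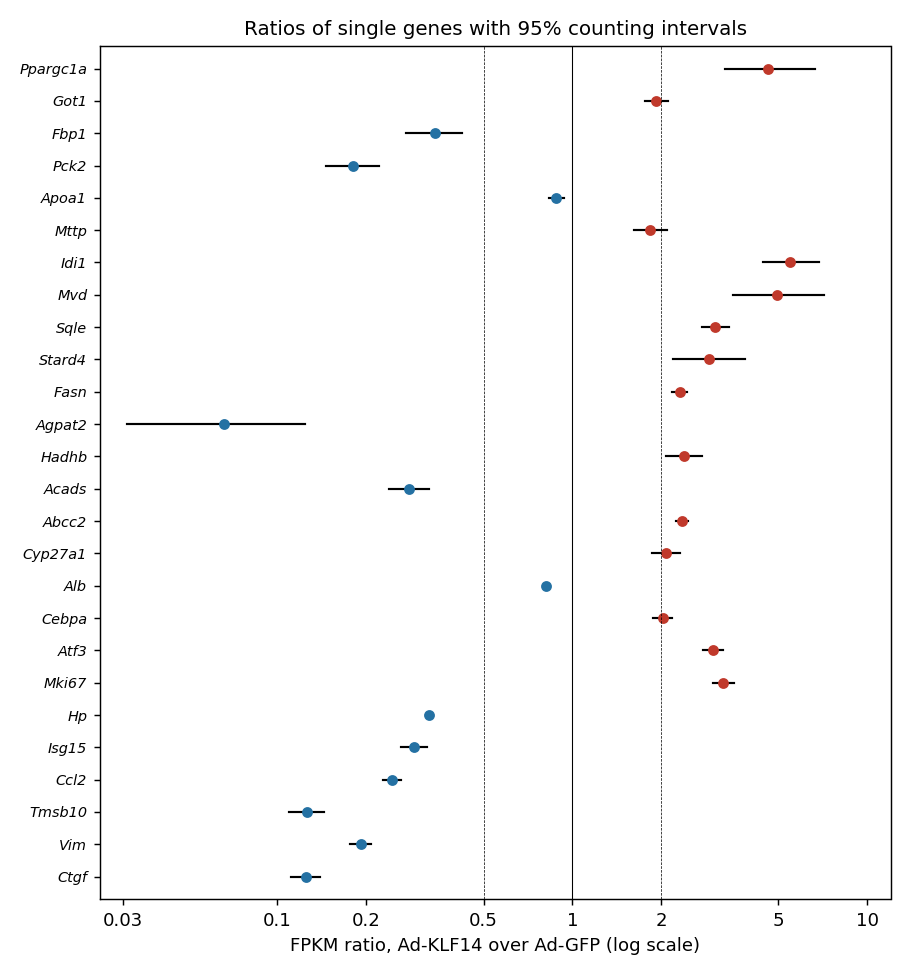
FPKM ratio of Ad-KLF14 over Ad-GFP for selected genes on a log axis, with points for the ratio and bars for its 95% counting interval, which covers counting error only; the solid line marks equal levels and the dashed lines 2-fold differences. Idi1 lies at 5.48 and Ctgf at 0.125, with Apoa1 near the line at 0.882.

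Genes of innate immunity were lower with Ad-KLF14. Of 31 interferon response genes 30 were below 0, 13 of them at least 2-fold lower and none at least 2-fold higher, and the median of −0.81 was at percentile 0. Ifi44 was 4.79-fold lower (6.38 against 30.6 FPKM), Oasl2 3.95-fold, Ifit1 3.78-fold and the ubiquitin-like Isg15 3.44-fold (56.7 against 195 FPKM, interval 3.10 to 3.81). Of 25 NF-kB target and chemokine genes 19 were below 0 and 6 above, with a median of −0.60 (percentile 0.03). Among them 7 were at least 2-fold lower and 0 at least 2-fold higher. The monocyte chemoattractants Ccl2 (116 against 476 FPKM) and Ccl7 were 4.09-fold and 3.15-fold lower, and Bcl3 was 2.85-fold lower. Acute phase genes had a median of −0.38 (percentile 1.07) and a mean of −0.59, with 5 of 21 at least 2-fold lower, and came inside the limits at percentile 2.81 against random lists not matched on expression. Haptoglobin, Hp, was at 729 against 2233 FPKM (3.06-fold lower), the lipopolysaccharide-binding protein Lbp was 6.63-fold lower and C-reactive protein, Crp, 4.25-fold lower. The 13 antigen presentation genes had a median of −0.39 at percentile 3.67, inside the limits but outside them under 6 alternatives. Psme1, Psmb9 and Tap1 were 3.85-fold, 2.22-fold and 2.12-fold lower. This list shares Psmb8, Psmb9 and Tap1 with the interferon list. Macrophage markers, the other immune signal in such cultures, had a median of 0.11 over 14 genes (percentile 81.2) and went both ways, with Cd68 2.25-fold higher and Mpeg1 2.34-fold lower.

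The list of cytoskeletal and hepatocyte dedifferentiation genes was lower as well, though not in every member. Of 28 measured members 27 were below 0 and 9 at least 2-fold lower, and the median of −0.81 was at percentile 0. The actin-binding peptide gene Tmsb10 was at 33.9 against 269 FPKM (7.93-fold lower, interval 6.93 to 9.10), the intermediate filament gene vimentin, Vim, at 33.9 against 177 FPKM (5.21-fold lower), Spp1 at 191 against 681 FPKM (3.57-fold lower) and galectin 1, Lgals1, 2.93-fold lower. Named after their values were seen, Afp, Krt23 and Cd24a had ratios of 0.872, 0.894 and 0.733. Their counting intervals held 1, so no difference was detectable in them. Tuba1c in the same list was 1.77-fold higher. Genes of TGF-beta signalling and matrix had a median of −0.71 over 20 members (percentile 0), or −0.35 (percentile 0.3) over 24 members without the filter on low values, with 6 at least 2-fold lower and 1 at least 2-fold higher. Ctgf was 8.02-fold lower (12.5 against 100.3 FPKM, interval 7.16 to 9.01) and Thbs1 7.19-fold lower, while the inhibitor of differentiation Id2 was 2.96-fold higher. The bile duct markers Spp1, which is also in the cytoskeletal list, and Cldn4 (2.63-fold lower) went with them, and the 5 measured cholangiocyte markers had a median of −0.44 at percentile 11.1, inside the limits but below them under 3 alternatives.

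**Figure D3:**
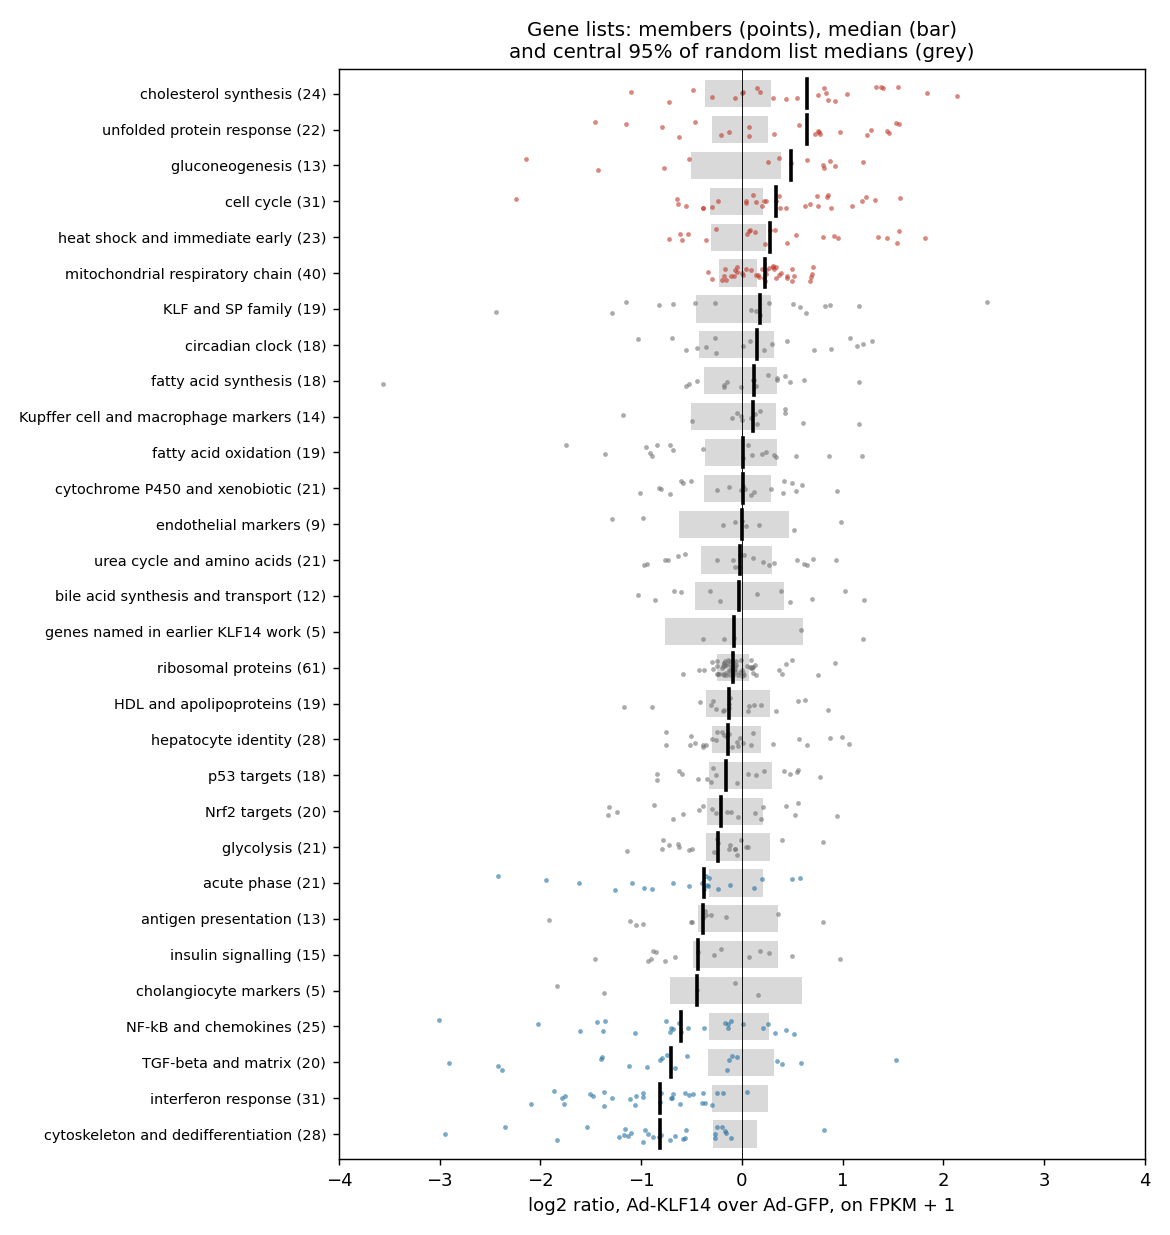
Log2 ratio on FPKM + 1 of the members (points) of the 30 gene lists with at least 5 measured genes, with the number measured in brackets, the list median (black bar) and the central 95% of medians of random lists (grey). Red and blue lists lie outside that range and grey ones inside; the cytoskeletal list is lowest at −0.81 and cholesterol synthesis highest at 0.65, and Klf14 itself, at 13.31, falls outside the axis.

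Genes of the unfolded protein response, heat shock and immediate early genes, the cell cycle and the respiratory chain were higher. Of 22 genes of the unfolded protein response 6 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.65 (percentile 100) and a mean of 0.40 (percentile 99.2). Atf3 was 2.99-fold higher (115 against 38.4 FPKM), Ppp1r15a, which restores translation after stress, 2.96-fold, and Sdf2l1 3.0-fold. The 2 lower genes were Trib3 and Pdia6, the latter 2.25-fold lower and named after its values were seen. Atf3 is also in the heat shock and immediate early list. Heat shock and immediate early genes had a median of 0.28 over 23 members (percentile 98.8), with 5 at least 2-fold higher, among them Fosb (7.10-fold, 4.99 against 0.702 FPKM) and Egr1 (3.0-fold). Under 3 alternatives this list came inside the limits. Hspa1b was 3.09-fold higher and has a near-identical copy, Hspa1a, so its value is uncertain. Cell cycle genes had a median of 0.34 over 31 members (percentile 99.8), with 23 above 0 and 8 below. Among them 5 were at least 2-fold higher and 1 at least 2-fold lower. The proliferation marker Mki67 was 3.25-fold higher (21.8 against 6.70 FPKM), the replication licensing gene Cdc6 2.71-fold and Rrm2 2.37-fold. Thymidine kinase 1, Tk1, was 5.71-fold lower. The mitotic genes Ccnb2 and Bub1b were 1.82-fold and 1.70-fold lower and Ccnb1 1.73-fold higher, all named after their values were seen. The 40 genes of the mitochondrial respiratory chain were slightly higher together, with a median of 0.23 (percentile 99.5), 29 members above 0 and none at least 2-fold apart. Cox8a and Cycs were 1.63-fold and 1.75-fold higher in it.

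Hepatocyte identity genes stayed close to each other in both libraries. Of 28 members 27 were under 2-fold, and the median of −0.14 was at percentile 26.1. The liver transcription factor genes Cebpa and Foxa3 were 2.02-fold and 1.90-fold higher, both under 2-fold with the pseudocount, and the fibrinogen gene Fgg was 1.69-fold lower. Drug metabolism genes had a median of 0.01 over 21 members (percentile 60.8) and a mean of −0.07, with Fmo5 2.36-fold lower and Gstm1 1.94-fold higher. Urea cycle and amino acid genes had a median of −0.02 over 21 members (percentile 53.9), with Cbs 1.98-fold higher. The 18 p53 targets (median −0.15, percentile 17.6) held no gene at least 2-fold apart. Nrf2 targets (median −0.20 over 20 members, percentile 15.6) held 3 genes at least 2-fold lower, Mgst3, G6pdx and Gsta4. The 61 ribosomal protein genes had a median of −0.09 (percentile 55.0), which was 0.06 once a trend with expression was removed.

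The clock genes Nr1d1, Per2, Per1 and Cry1 were 2.53-fold, 2.99-fold, 2.44-fold and 2.19-fold higher, and Npas2, named after its values were seen, was 4.62-fold lower (0.408 against 1.88 FPKM). These are the 4 circadian genes at least 2-fold higher and the 1 at least 2-fold lower, and the 18 measured together were inside the limits (median 0.15, percentile 85.0). In the KLF and SP family, Klf13 was 7.28-fold lower (2.40 against 17.4 FPKM), Klf16 was 2.63-fold lower, and Sp9 was at 4.56 against 0.0314 FPKM, from 143 reads and 1 read (145-fold, interval 25.6 to 5769). The 19 measured family members had a median of 0.18 (percentile 91.3) and a mean of 0.73 that includes Klf14. Of the genes named in earlier work on KLF14, Ppargc1a was the only measured member at least 2-fold apart. Tgfbr2 was 1.52-fold higher, Plk4 1.41-fold lower and Sphk1 at 3.24 against 3.48 FPKM. These 5 measured genes had a median of −0.08 (percentile 49.2) and a mean of 0.23.

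The 9 measured endothelial markers had a median of 0.01 (percentile 60.6) and a mean of −0.09, and none was above 5.86 FPKM. They went both ways, with Oit3 3.91-fold lower (0.990 against 3.87 FPKM), Flt4 2.46-fold lower, Bmp2 2.54-fold higher and Pecam1 1.81-fold higher. Stellate cell and fibroblast markers had 3 measured members, with Ecm1 2.61-fold lower and Tagln 1.93-fold higher. No lymphocyte or neutrophil marker reached a mean of 1 FPKM, and the erythroid Alas2 was at 1.5 against 1.65 FPKM. Of 18 retina markers 3 reached it, and Gnat1 was at 4.75 against 0.881 FPKM. Over all 30 lists with at least 5 measured genes, 6 lay above the limits, 5 below and 19 inside, where 1.5 lists would lie outside by chance if genes were independent.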

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

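The removal of Klf14 reads, the counting interval, and the GC and length corrections were chosen after seeing the data. Of 387 list medians under the alternatives 369 stayed on their side of the limits, and none that had been called changed sign. Of 877 log2 ratios of named genes 780 stayed within their counting interval and 97 moved beyond it, and none of a gene at least 2-fold apart changed sign. The share of higher genes among those at least 2-fold apart was 41.5%, and 48.1% at most, under scaling to 1000000. With a pseudocount of 5 FPKM, 295 genes were higher and 467 lower, as a larger pseudocount shrinks every ratio. A 1.5-fold limit gave 2079 higher and 2598 lower genes, and a 4-fold limit 56 and 112. Scaling to 1000000 gave 1210 higher genes and set Klf14 at 27611 and 0.602, against 13343 in Ad-KLF14 with the trimmed mean, 13272 with the upper quartile and 13426 without its own reads in the total. Scaling to 1000000 both raises all values against the fixed filter and pseudocount and shifts the libraries against each other, and the cause of the higher count was not tested. Requiring a counting interval without 1 left 774 higher and 1096 lower genes.

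Antigen presentation came below the limits with a pseudocount of 5 FPKM (−0.37), scaling to 1000000 (−0.39), no filter (−0.40), a mean of at least 5 FPKM (−0.44), the mean of members (−0.50) and the length correction (−0.40). Cholangiocyte markers came below them with scaling to 1000000 (−0.89), no filter (−0.44) and the mean (−0.71), and insulin signalling with a mean of at least 5 FPKM (−0.55), the GC correction (−0.44) and the length correction (−0.43). Heat shock genes came inside them with a mean of at least 5 FPKM (0.23), unmatched lists (0.28) and the GC correction (0.27), acute phase genes with unmatched lists (−0.38), and gluconeogenesis with the mean (0.12). The KLF and SP family came above them with the mean (0.73), which includes Klf14. For the lists the cause was not tested. The planned choice among several values of a symbol gave nothing, as each symbol had 1 value. No paired analysis was possible because each group holds 1 library, and leaving out a library was not possible either. Depth limits what can be said of genes with few reads, such as Pck1 and G6pc.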

Other observations

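The gene groups described next were all chosen after values had been seen, and of these the V-ATPase, proteasome, SRF and YAP-TEAD lists lay outside the limits. Of 17 measured subunits of the V-ATPase, the proton pump of lysosomes, 4 were at least 2-fold higher with Ad-KLF14 and 0 at least 2-fold lower (median log2 ratio 0.41, percentile 99.2), led by Atp6v1a (93.7 against 26.3 FPKM, 3.56-fold) and Atp6v1b2 (2.46-fold). The 31 proteasome genes had a median of 0.20 (percentile 99.7), with none at least 2-fold apart and Psmd13 highest at 1.70-fold, while the immunoproteasome gene Psmb9 was lower. Among the 8 E2F factors, E2f8 and E2f7 were 3.39-fold and 2.18-fold higher beside E2f2 (list median 0.47, percentile 96.3). The CDK inhibitor genes Cdkn1c and Cdkn2c were 4.92-fold and 4.01-fold higher and Cdkn2b was 8.31-fold lower (median over 6 genes 0.39, percentile 93.3). Of 13 lipid droplet genes, the hormone-sensitive lipase gene Lipe was 4.97-fold higher and Fitm2, which helps form droplets, 3.12-fold higher, whereas G0s2 and Cideb were 23.1-fold and 2.49-fold lower (median −0.04, percentile 43.8). The 13 mitochondrially encoded genes had a median of 0.17 (percentile 91.0).

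Targets of the actin-regulated factor SRF were lower, with 11 of 25 at least 2-fold lower (median −0.95, percentile 0), such as Cnn2 (9.93-fold), Tpm2 (23.1-fold) and Fhl2 (5.25-fold). In that list 4 went the other way, Fosl1 (1.98-fold higher), Tagln (1.93-fold), Itga5 (1.49-fold) and Actn4 (1.40-fold), where all but Tagln were named after their values were seen. Of 19 targets of YAP and TEAD 5 were at least 2-fold lower and 1 at least 2-fold higher (median −0.55, percentile 0.55). Ankrd1 was 6.24-fold and Igfbp3 13-fold lower. The YAP and TEAD list also holds F3, described above, and Cyr61 of the TGF-beta list, so its percentile is not independent of those results. Some genes had reads only in the Ad-KLF14 library. Esx1, a homeobox gene, had 63 reads against 0 (at least 21.3-fold higher against a floor of 3 reads, lower 95% counting limit 16.8) and the homeobox gene Pitx3 34 against 0 (at least 11.5-fold higher against that floor, lower counting limit 8.85).

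Of the tests below, those on cultures, library scaling, virus dose, GC content, transcript length, all sets of cell type markers and SRF and YAP targets were chosen after the results were seen. Of 12419 genes 1908 were at least 2-fold apart. Counting error is argued against as the source, since 100 redraws of both libraries from shared proportions gave at most 68 such genes. Differences between cultures or library preparations unrelated to the virus insert cannot be told apart from an effect of KLF14, because there is 1 library per group. Both may contribute.

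The interferon and NF-kB lists were lower. Library scaling, and the reads taken by Klf14, are argued against by the size of the rescalings, which left the interferon median at −0.76 or lower and the NF-kB median at −0.56 or lower. Fewer macrophages would lower their markers together, but their median was 0.11 (95% bootstrap interval −0.05 to 0.43). This lay above the bound of −0.41 set from the interferon median. Even so, the most abundant marker, Cd14, was itself lower at 217 against 306 FPKM. Bootstrap intervals here and below were drawn over marker genes within these 2 libraries, so they do not cover differences between cultures. A difference in virus dose between the cultures cannot be told apart from an effect of KLF14, since 0 adenoviral or GFP genes are listed. Lower interferon and NF-kB output with KLF14 may be the source, and is untested beyond this.

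The cytoskeletal and TGF-beta lists were lower too. Biases of GC content and transcript length are argued against, since the list nearest to 0 had a median of −0.66 and −0.71 once each trend was removed, at percentile 0.01 or lower. Fewer macrophages are argued against by a median of 0.11 over their 14 markers in these 2 libraries. Its bootstrap interval over the markers was −0.05 to 0.43, above a bound of −0.41 set from the cytoskeletal median. Fewer endothelial cells stay open (9 markers, median 0.00595, interval −0.99 to 0.52). So do fewer stellate or bile duct cells (7 markers without Spp1, median −0.24, interval −1.22 to 0.16). Lower output of SRF and YAP-TEAD targets may contribute but stays open, as 34 targets outside the fixed lists, and outside the 60 genes with the most extreme ratios each way, had a median of −0.65 at percentile 0, with 28 below 0, whereas the SRF-driven immediate early genes Fosb, Egr1, Fos, Junb and Ier2 had a median of 0.80 with 4 of 5 above 0. Part of these targets, and the immediate early genes, were chosen and named after their values were seen, and there are no replicates, so this remains a hypothesis.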
